A study of Aspergillus fumigatus with 4 samples.

How the data were processed

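RNA of 4 cultures of Aspergillus fumigatus CEA10 was measured by sequencing, with 1 library per time point. Per the labels' protocols, conidia were grown for 6 h at 37 °C and 300 rpm in 400 ml of glucose minimal medium, which gave the 0 h normoxia sample. For hypoxia the germlings were pelleted for 8 min at 3000 rpm, resuspended in 50 ml, added to 150 ml of medium preconditioned in hypoxia, and shaken at 150 rpm in 1% oxygen, 5% CO2 and 94% nitrogen for 12, 24 or 36 h. Per the labels, the 24 h and 36 h cultures came from 1 split starting culture and the 12 h culture from a whole one. RNA of all time points was extracted at the same time, and poly(A) RNA was selected with oligo(dT), fragmented and sequenced on an Illumina instrument, per the labels.

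The deposited table gives 4 values per gene in a unit its header does not name. They were taken as RPKM made by the authors, because each deposited value times the deposited length was a whole multiple of 1 step per library, and these products summed to nearly the same total in the 4 libraries. The deposited length in bases, headed as an exon length, equalled gene end minus gene start for all 9703 genes, so introns are counted in it and lengths are called spans here. The deposited log2 columns, per the file headers, are the log2 ratio of each hypoxia library to 0 h. They matched log2 ratios computed from the deposited RPKM, were empty for 730.0, 537.0 and 565.0 genes with a value of 0, and were not used further. The aligner, the counting tool, the read filters and the genome build are not given in the sources used here. The gene models are named after strain Af293 in the deposited table while the labels give strain CEA10, so effects of strain differences on counting were not analysed here.

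Whole reads per gene were worked out from the RPKM values and the spans, and 100% of values lay within 0.01 reads of a whole number in every library. Depth was 10993291, 5552572, 9152473 and 5931305 reads at 0, 12, 24 and 36 h, and 460, 600, 300.0 and 354 genes had 0 reads, of which 171 had 0 reads in all 4 libraries. In a gene of 1 kb, 3 reads equal 0.273, 0.5403, 0.328 and 0.506 RPKM, which was the floor used where a gene had 0 reads in a library. The median RPKM over all genes was 18.7, 11.2, 19.6 and 18.3. The 10 most abundant genes took 10.01%, 15.03%, 10.7% and 10.4% of reads, and the 17 genes of the mitochondrial genome 0.145%, 0.278%, 0.064999% and 0.244%.

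Each hypoxia library was compared with the 0 h library, and 24 h with 12 h and 36 h with 24 h. The log2 difference was log2(RPKM + 1) in the later library minus the same in the earlier one. A gene counted as measured where the larger of the 2 values was at least 1 RPKM, and as higher or lower where the log2 difference was at least 1 either way, which is 2-fold on RPKM + 1. With 1 library per group no test was made. Folds of single genes are ratios of RPKM without the added 1, with 95% intervals from the exact binomial (Clopper-Pearson) interval of the reads of the gene in the 2 libraries. Genes at least 2-fold higher or lower at all 3 times were counted beside the number that independent lists share and beside 20 simulations of unchanged libraries that share the 0 h library.

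The comparisons, thresholds, 27 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The lists held 1072 genes, were drawn up from product names and known locus tags, and covered sterol biosynthesis, hypoxia regulators, heme biosynthesis, fermentation, glycolysis, the tricarboxylic acid cycle, the respiratory chain with ATP synthase, alternative oxidase, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis and tRNA synthetases. They also covered iron uptake with siderophores, nitrogen oxide metabolism, the cell wall, the gliotoxin cluster, secondary metabolism backbones, conidia with melanin, oxidative stress, heat shock with chaperones, beta-oxidation with the glyoxylate cycle, the GABA shunt, DNA replication with histones, the proteasome, sugar transporters, secreted carbohydrate hydrolases and proteases. For the 25 lists of at least 3 measured genes, the median log2 difference was placed among 10000 random lists of the same size, matched on 10 bins of mean expression. A list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5, where 5% of lists fall by chance. Hypoxia regulators and alternative oxidase are given by gene.

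Genes were named by rule: the 10 largest log2 differences each way in each comparison with 0 h and the 5 largest each way in 24 h against 12 h and 36 h against 24 h, among genes of at least 10 RPKM in the higher library with an informative product name, every gene given by locus tag in a list whose product name did not contradict it, and up to 4 members of each list with the largest difference. This gave 244 genes, part of which are named in the text. Gene symbols came from a RefSeq gene table of assembly ASM265v1 (Af293), in which 9617 locus tags matched and 1401 had a symbol. Coordinates are those of the deposited table on its own numbered sequences, with starts taken as 0-based and given as 1-based, and spans of 6 genes overlapped another gene.

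Alternatives were pseudocounts of 0.1 and 10, no filter and a filter of 10 RPKM on the larger value, a 4-fold threshold, median-of-ratios, TMM and upper-quartile scaling of the libraries, and list means. Alternatives added after the data were seen were thinning of all libraries to the depth of 12 h, the comparison over time without the 24 h library, and lists without spans under 800 bp. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedure was tested on simulated data of 9703 genes at these depths, with counting error only and with changes only in genes of at least 10 RPKM. There 98% to 100% of genes changed 3-fold and 100% of those changed 8-fold were recovered, and 19 to 41 of 9503 unchanged genes were called. The simulation held no spread between cultures, so these counts are not error rates of the comparisons. Sequence motifs, reads and alignments were not analysed here.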

Results

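Poly(A) RNA of Aspergillus fumigatus strain CEA10, a filamentous mould and opportunistic human pathogen, was sequenced in 4 libraries. Germlings grown for 6 h in liquid glucose minimal medium in air were the 0 h normoxia sample, and cultures then kept in 1% oxygen and 5% CO2 for 12 h, 24 h and 36 h were the hypoxia samples. There was 1 library per time point, so no difference below has a replicate check or a p-value. Intervals and detection floors cover counting error only, and list percentiles describe these libraries. Apart from oxygen, the hypoxia cultures differed from the germlings in the 5% CO2, the transfer to preconditioned medium and their age. They had also been pelleted and resuspended, and were shaken at 150 rpm where the germlings were shaken at 300 rpm. No normoxia library of 12 h, 24 h or 36 h was analysed here, so effects of these differences cannot be told apart from those of oxygen. The deposited values were RPKM for 9703 genes, and the library totals worked out from them were 10993291 reads at 0 h, 5552572 at 12 h, 9152473 at 24 h and 5931305 at 36 h. At these depths 1 read in a gene of 1 kb was worth 0.09096 to 0.1801 RPKM. The median of all measured genes lay at a log2 difference of -0.64 at 12 h, -0.094 at 24 h and -0.016 at 36 h from 0 h. Values for 12 h are therefore given relative to that median where stated. RPKM folds are unadjusted for it.

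Several genes that are known for the fungal response to low oxygen were already among the most abundant transcripts of the 0 h germlings. The flavohemoprotein fhpA (AFUA_4G03410, sequence 104, 264322 to 265563), which detoxifies nitric oxide, had the highest RPKM of all genes at 0 h and stood at 28452, 29059.8, 21298 and 16636 RPKM at 0, 12, 24 and 36 h. The coproporphyrinogen III oxidase hem13 (AFUA_1G07480, sequence 98, 2109870 to 2111253), an oxygen-requiring enzyme of heme synthesis, stood at 8095, 7014, 5446 and 6522 RPKM, and was lower at 12 h on the deposited scale but 0.43 log2 units above the median of all genes. The C-4 methyl sterol oxidase erg25A (AFUA_8G02440, sequence 102, 138672 to 139672), an oxygen-requiring enzyme of ergosterol synthesis, stood at 5545, 6194, 6809 and 9137 RPKM. It was 1.65-fold (95% interval 1.63 to 1.67) higher at 36 h. The regulator gene srbB (AFUA_4G03460) stood at 3822, 5540.1, 3685 and 2729 RPKM and srbA (AFUA_2G01260), which encodes the sterol regulatory element binding protein, at 149, 214, 121 and 245 RPKM. Relative to the median of all genes, srbB lay 1.17 log2 units higher at 12 h, 0.041 at 24 h and -0.47 at 36 h. The same values of srbA were 1.16, -0.20 and 0.73.

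Named genes of ethanol fermentation and of the alternative respiratory pathway passed 2-fold at different times. The alternative oxidase gene aoxA (AFUA_2G05060, sequence 57, 1391181 to 1392358), whose product passes electrons from ubiquinol to oxygen, stood at 1341, 6424, 4104 and 3424 RPKM, which was 4.79-fold (95% interval 4.71 to 4.88) higher than 0 h at 12 h and 2.55-fold (95% interval 2.504 to 2.604) higher at 36 h. The alcohol dehydrogenase alcC (AFUA_5G06240) stood at 1703, 2173, 2579 and 4696 RPKM and the pyruvate decarboxylase pdcA (AFUA_3G11070) at 2052, 5059, 2230.2 and 3003 RPKM. The gene alcC was 2.76-fold (95% interval 2.71 to 2.81) higher at 36 h, and pdcA was 2.46-fold (95% interval 2.43 to 2.496) higher at 12 h and 1.09-fold (95% interval 1.07 to 1.101) higher at 24 h. The azole target genes of sterol 14-alpha demethylation lay lower in all 3 hypoxia libraries. The gene cyp51A (AFUA_4G06890) stood at 926, 396, 626 and 765 RPKM and cyp51B (AFUA_7G03740) at 698, 103, 433 and 365 RPKM, or -0.58 and -2.12 log2 units from the median of all genes at 12 h.

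**Figure D1:**
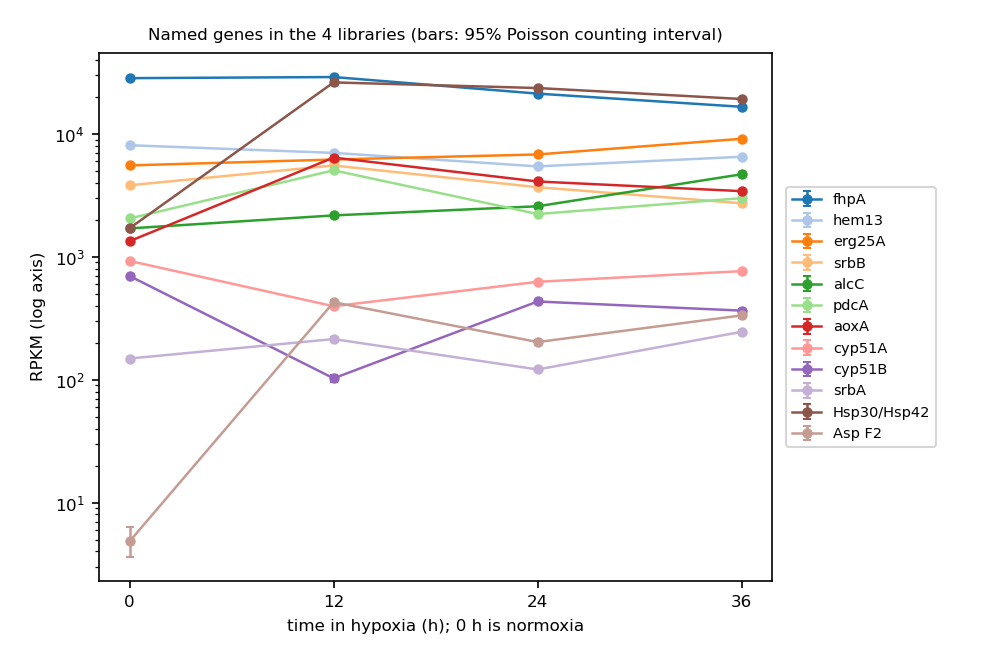
RPKM (log axis) of 12 named genes in the 4 libraries, against hours in hypoxia, where 0 h is normoxia. Points are single libraries and bars are 95% Poisson counting intervals, which do not include spread between cultures. The fhpA gene stands at 28452 RPKM before hypoxia, and the Hsp30/Hsp42 gene at 1709 RPKM at 0 h and 26276 RPKM at 12 h.

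The comparison of 12 h hypoxia with 0 h asked which transcripts differ after the shortest exposure. The named genes with the largest differences included the following. The copper resistance-associated P-type ATPase (AFUA_3G12740, sequence 93, 690509 to 694273) was at 13.6 RPKM at 0 h and 1126 RPKM at 12 h, 82.96-fold (95% interval 76.3 to 90.4) higher. The major allergen Asp F2 (AFUA_4G09580, sequence 96, 1428641 to 1429638) was at 4.83 RPKM at 0 h and 427 RPKM at 12 h, 88.3-fold (95% interval 67.3 to 118) higher. An extracellular lipase (AFUA_8G02530, sequence 102, 117627 to 119315) was 115-fold (95% interval 90.7 to 148) higher, an indoleamine 2,3-dioxygenase family gene (AFUA_7G02010) 106-fold (95% interval 87.5 to 130.05) higher and the cyclin Pcl1 (AFUA_1G04750) 60.4-fold (95% interval 51.6 to 71.2) higher. The Ctr copper transporter family gene crmD (AFUA_3G13660) had 0 reads at 0 h and 36.3 RPKM at 12 h, at least 94.4-fold higher against a floor of 3 reads.

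Heat shock proteins and chaperones, which assist protein folding, included abundant genes that were higher at 12 h. The Hsp30/Hsp42 gene (AFUA_3G14540, sequence 93, 225422 to 225964) was 15.4-fold (95% interval 15.1 to 15.7) higher, at 26276 RPKM, and the Hsp30-like gene (AFUA_6G06470) 11.8-fold (95% interval 11.5 to 12.04) higher, at 16103 RPKM. Hsp20/Hsp26 (AFUA_5G10270) was 33.05-fold (95% interval 28.002 to 39.3) higher and the chaperonin Hsp78 (AFUA_1G11180) 6.91-fold (95% interval 6.75 to 7.08) higher. Relative to the median of all genes, 16 of the 30 measured list members were at least 2-fold higher and 3 at least 2-fold lower, against 12 higher and 8 lower on the deposited scale. The list median lay 1.28 log2 units above that of all genes, at percentile 99.9 of random matched lists.

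Iron uptake and siderophore genes, which encode high-affinity iron acquisition, had 16 of 24 members at least 2-fold above the median of all genes at 12 h and 0 at least 2-fold below it, against 13 higher and 2 lower on the deposited scale. The list median lay 1.66 above that of all genes (percentile 100). The siderochrome-iron transporter Sit1 (AFUA_7G06060) was 7.41-fold (95% interval 6.58 to 8.36) higher and the iron permease ftrA (AFUA_5G03800) 4.15-fold (95% interval 3.89 to 4.44) higher. The ornithine oxygenase sidA (AFUA_2G07680), which opens siderophore synthesis, was 2.53-fold (95% interval 2.19 to 2.93) lower, at a log2 difference of -0.67 from the median of all genes. Secondary metabolism backbone genes had 20 of 27 members at least 2-fold above the median of all genes, with a list median 1.76 above it (percentile 100) and 15 higher and 1 lower on the deposited scale. With median-of-ratios factors their list median was 1.38. Examples are the peptide synthases Pes1 (AFUA_1G10380), 12.95-fold (95% interval 11.4 to 14.7) higher, and SidE (AFUA_3G03350), 12.4-fold (95% interval 10.5 to 14.8) higher.

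The gliotoxin cluster, whose product is an immunosuppressive toxin, had 6 of its 12 genes measured at 12 h. On the deposited scale 3 of the 6 were at least 2-fold higher and 0 lower. All 6 lay at least 2-fold above the median of all genes (list median 1.53 above it, percentile 97.8). Subtracting that median lifts genes near 0 RPKM by 0.64 log2 units even without a change. With median-of-ratios factors the list median was 1.38, over 7 measured genes. Among the 6 genes was the efflux transporter gliA (AFUA_6G09710), at 0.223, 8.29, 3.76 and 5.17 RPKM at 0, 12, 24 and 36 h. The peptide synthase gliP (AFUA_6G09660) was not among the measured genes at 12 h and stood at 0.587, 0.748, 0.672 and 1.11 RPKM. Secreted carbohydrate hydrolases had 36 of 63 members at least 2-fold above the median of all genes (list median 1.13 above it) and 1 below it, against 20 higher and 11 lower on the deposited scale, for example a beta-glucosidase (AFUA_3G00230), 25.9-fold (95% interval 19.2 to 35.8) higher. Fermentation genes lay 0.83 above the median of all genes (percentile 99.8, 17 of 39 at least 2-fold above it and 1 below it, against 12 higher and 4 lower on the deposited scale). Sugar transporters lay 0.65 above it (percentile 99.9), with members on both sides: a hexose transporter (AFUA_3G00200) was 171-fold (95% interval 78.1 to 469) higher and a monosaccharide transporter (AFUA_2G14590) 25.6-fold (95% interval 22.4 to 29.3) lower. On the deposited scale 13 higher and 16 lower members passed 2-fold, their median was 0.0071, and it turned negative for the list mean (-0.0082) and with no filter on low values (-0.019). The beta-oxidation and glyoxylate list lay 0.62 above it (percentile 98.3) and included isocitrate lyase AcuD (AFUA_4G13510), 12.8-fold (95% interval 10.8 to 15.4) higher. Its median on the deposited scale was -0.019, with 6 higher and 6 lower members, so its direction turned with the scaling, and its percentile was 97.02 for the list mean and 96.5 with no filter on low values.

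The oxidative stress list and the conidia and melanin list also lay above the median of all genes at 12 h, by 0.98 (percentile 99.3) and 1.48 (percentile 99.9). With median-of-ratios factors the list medians were 1.00 and 0.95 in that order. On the deposited scale the oxidative stress list had 8 higher and 10 lower of 31 members (14 and 4 relative to the median of all genes) and the conidia and melanin list 7 higher and 4 lower of 14 (8 and 2). A glutathione S-transferase (AFUA_2G00590) was 26.9-fold (95% interval 24.3 to 29.8) higher and the manganese superoxide dismutase sod3 (AFUA_1G14550) 35.2-fold (95% interval 22.9 to 56.8) higher. Conidial pigment genes abr2 (AFUA_2G17530) and pksP (AFUA_2G17600) were 151-fold (95% interval 41.2 to 1262) and 3.33-fold (95% interval 3.02 to 3.67) higher, while the conidiation regulators brlA (AFUA_1G16590) and flbC (AFUA_2G13770) were 4.58-fold (95% interval 2.68 to 8.41) and 8.49-fold (95% interval 5.41 to 14.1) lower. The abr2 fold rests on few reads at 0 h, where it stood at 0.088 RPKM. Neither list stood apart without genes of spans under 800 bp, where the deposited-scale medians were -0.17 and -0.45, against 0.34 and 0.84 with them. With the members at 0 reads set at their bound, the conidia and melanin median was 0.35.

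Lists of ribosome, respiratory chain and DNA replication genes had medians below that of all genes at 12 h. Of 96 cytosolic ribosomal protein genes, 67 were at least 2-fold lower and 0 higher, and 45 were at least 2-fold below the median of all genes. The list median lay -0.91 from that of all genes. Ribosomal protein S28e (AFUA_7G04490, sequence 99, 1032968 to 1033215) was at 584 RPKM at 0 h and 7.26 RPKM at 12 h, 80.4-fold (95% interval 43.6 to 168) lower, and S10b (AFUA_6G12660) was 18.4-fold (95% interval 17.1 to 19.9) lower. The span of S28e is under 800 bp, and genes of such spans were lower as a group at 12 h. The medians of ribosome biogenesis genes and of mitochondrial ribosomal protein genes lay -1.12 and -1.12 from that of all genes, with 36 of 66 and 12 of 21 members at least 2-fold below it. The snoRNP protein Snu13 (AFUA_2G05950) was 25.5-fold (95% interval 18.2 to 36.98) lower. DNA replication and histone genes lay -0.72 from the median of all genes (percentile 0.1), with 7 of 35 members at least 2-fold below it, against 27 on the deposited scale, and histone H2B (AFUA_3G05350) was 4.597-fold (95% interval 4.28 to 4.94) lower.

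The respiratory chain and ATP synthase list, whose median lay -0.61 from that of all genes, split by genome at 12 h. Relative to the median of all genes, 21 of its 69 members were at least 2-fold lower and 10 at least 2-fold higher. On the deposited scale 40 of 59 nuclear genes were at least 2-fold lower, with a median log2 difference of -1.38. A gene annotated as an NADH-ubiquinone oxidoreductase 105 kDa subunit (AFUA_6G02960) was 65.005-fold (95% interval 35.2 to 136) lower and cytochrome c cycA (AFUA_2G13110) 3.38-fold (95% interval 3.22 to 3.55) lower. Of the 10 genes of the list encoded in the mitochondrial genome, 8 were at least 2-fold higher, with a median of 2.31. The RNA was poly(A)-selected, and how evenly this selection kept mitochondrial transcripts in the 4 libraries was not tested. ATP synthase subunit 6 (AFUA_MITO015) was at 25.9 RPKM at 0 h and 1433 RPKM at 12 h, 55.3-fold (95% interval 48.3 to 63.6) higher. The sterol biosynthesis list did not stand apart at 12 h (percentile 3.62) although 11 of 30 members were at least 2-fold below the median of all genes. It stood lower for the list mean (percentile 0.02) and with a pseudocount of 10 (0.65). The sterol isomerase erg2 (AFUA_1G04720) was 11.2-fold (95% interval 8.83 to 14.3) lower.

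In all, 8571 genes were measured at 12 h, of which 1219 were at least 2-fold higher and 3064 at least 2-fold lower on the deposited scale. With median-of-ratios factors, which moved the 12 h library by 0.66 log2 units, the counts were 1998 and 1503. They were 1883 and 1627 with TMM factors, 1726 and 1855 at the same upper quartile, and 712 and 1602 with a pseudocount of 10.

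**Figure D2:**
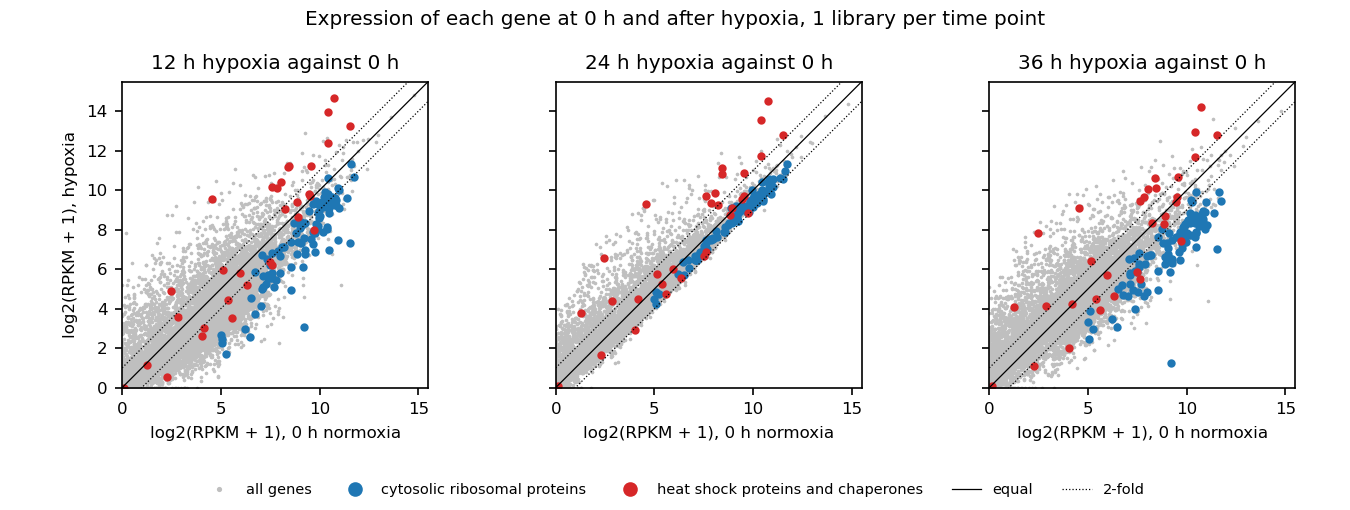
Each gene's log2(RPKM + 1) at 0 h (horizontal axis) and in 1 hypoxia library (vertical axis), with 12 h, 24 h and 36 h in separate panels. The solid line marks equal values and dotted lines a 2-fold difference. Cytosolic ribosomal protein genes (blue) lie below the solid line, with 67, 2 and 88 of 96 at least 2-fold lower at 12 h, 24 h and 36 h, and the most abundant heat shock genes (red) lie above it.

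The libraries also differed by gene span and by genome. Among nuclear genes with a mean of at least 10 RPKM, the 1012 genes of spans under 800 bp had a median log2 difference from 0 h of -0.92 at 12 h, -0.073 at 24 h and -0.55 at 36 h. The 1759 genes of spans over 2000 bp had medians of -0.55, -0.22 and -0.061. Matched on expression, short genes lay at -0.50, 0.14 and -0.54 from long genes. Of the 17 genes of the mitochondrial genome, 15 were higher at both 12 h and 36 h than at both 0 h and 24 h, against 16.3% of nuclear genes. Many ribosomal protein genes are short. The folds of S28e, given for several comparisons, may partly reflect this difference by span, which was not tested for single genes. Other named genes alternated between the same libraries. Relative to the median of all genes, Sss1 (AFUA_3G06901) lay at -3.08, 0.14 and -3.88 at 12, 24 and 36 h. The acidic ribosomal protein P1 lay at -3.33, -0.57 and -4.65, and the cytochrome c oxidase family gene AFUA_3G14440 at -2.98, 0.017 and -3.76. The same limit holds for their folds. Without spans under 800 bp, the cytosolic ribosomal list had medians of -1.503 at 12 h, -0.56 at 24 h and -1.96 at 36 h, against -1.54, -0.55 and -1.98 with them. This cut does not remove the difference by span. Genes of 800 to 1200 bp still had medians of -0.82 at 12 h and -0.40 at 36 h, against -0.46 and -0.033 for genes of at least 3000 bp. The list was not compared with genes of matched span, so how much of its fall goes with span is not decided.

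**Figure D3:**
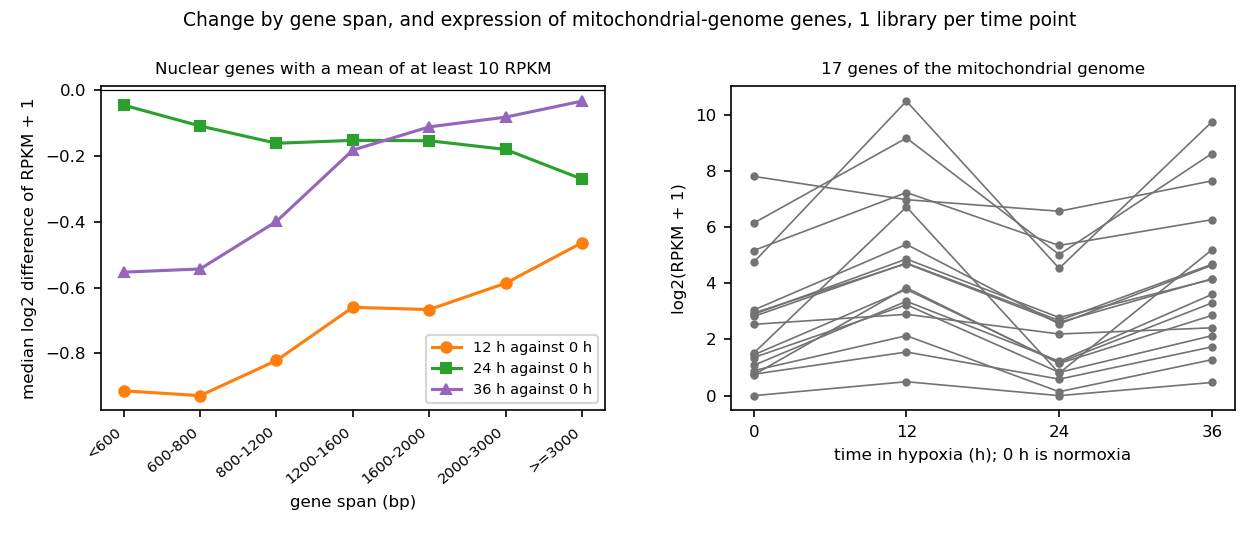
Left, median log2 difference of RPKM + 1 from 0 h (vertical axis) of nuclear genes with a mean of at least 10 RPKM, by gene span in bp (horizontal axis), for 12 h, 24 h and 36 h hypoxia. Right, log2(RPKM + 1) of the 17 genes of the mitochondrial genome against hours in hypoxia, 1 line per gene. Genes under 600 bp have medians of -0.91 at 12 h and -0.55 at 36 h, and genes of at least 3000 bp have medians of -0.46 and -0.033.

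The comparison of 24 h hypoxia with 0 h asked the same question of the middle exposure. The higher genes included several of those named at 12 h. The P-type copper ATPase was 33.1-fold (95% interval 30.5 to 36.1) higher, Asp F2 41.9-fold (95% interval 31.9 to 56.2) higher and the extracellular lipase 37.2-fold (95% interval 29.3 to 47.9) higher. A short-chain dehydrogenase/reductase (AFUA_8G06840, sequence 55, 853064 to 854277) had the largest log2 difference of the named genes at 24 h, 5.23, at 3.07 RPKM at 0 h and 151 RPKM at 24 h. The NADH-dependent flavin oxidoreductase (AFUA_7G06420) was 32.4-fold (95% interval 29.9 to 35.2) higher, the FMN reductase Lot6 (AFUA_7G06600) 31.96-fold (95% interval 22.9 to 45.9) higher and the protein phosphatase 2C ptcH (AFUA_4G00720) 48.1-fold (95% interval 28.9 to 86.5) higher. The Hsp30/Hsp42 and Hsp30-like genes were 13.8-fold (95% interval 13.6 to 14.1) and 8.91-fold (95% interval 8.72 to 9.12) higher.

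Of the gene lists, heat shock proteins and chaperones had a median log2 difference of 0.82 at 24 h, with 15 of 30 at least 2-fold higher and 1 lower, and a median of 0.41 without spans under 800 bp. The conidia and melanin list had a median of 1.13 (10 of 15 higher), secreted carbohydrate hydrolases 0.58 (24 of 66), iron uptake and siderophores 0.56 (7 of 25) and secondary metabolism backbones 0.50 (9 of 24). Sugar transporters (0.24) and fermentation genes (0.21) also stood apart. Secondary metabolism backbones were at percentile 93.2 with a pseudocount of 10 and 79.3 with no filter on low values, fermentation at 97.05 with a pseudocount of 0.1 and 96.4 without spans under 800 bp, and sugar transporters at 96.98 for the list mean, where none of the 3 stood apart. Examples are an endoglucanase (AFUA_2G14490), 18.3-fold (95% interval 12.9 to 26.7) higher, and a zinc-binding alcohol dehydrogenase (AFUA_8G02430), 24.6-fold (95% interval 21.8 to 27.9) higher.

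Lists that stood lower at 24 h did so by small amounts. Medians were -0.55 for cytosolic ribosomal proteins, -0.56 for ribosome biogenesis, -0.48 for tRNA synthetases, -0.45 for DNA replication and histones, and -0.45 for mitochondrial ribosomal proteins. They were -0.43 for sterol biosynthesis, -0.41 for the tricarboxylic acid cycle, -0.36 for the respiratory chain and -0.34 for the proteasome, whose percentile was 2.5 and was 3.52 without spans under 800 bp, 2.94 with a pseudocount of 0.1 and 2.65 with no filter on low values. Across these 9 lists, the genes at least 2-fold lower were 2 of the sterol list and 2 cytosolic ribosomal proteins. The autophagy endopeptidase Atg4 (AFUA_3G05340, sequence 93, 2788998 to 2789886) was the lowest named gene, 2.92-fold (95% interval 2.82 to 3.02) lower, followed by the ribosomal RNA processing gene Rrp17 (AFUA_7G04220), 2.56-fold (95% interval 2.25 to 2.92) lower. Orotate phosphoribosyltransferase (AFUA_2G11290) was 2.31-fold (95% interval 2.06 to 2.58) lower and a beta-tubulin tub2 (AFUA_7G00250) 2.39-fold (95% interval 2.01 to 2.86) lower.

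In all, 1120 of 8660 measured genes were at least 2-fold higher at 24 h and 56 at least 2-fold lower, with 392 and 0 at the 4-fold threshold. The counts were 510 and 10 with a pseudocount of 10, and 89 genes were lower with a pseudocount of 0.1 and 31 with TMM factors.

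The comparison of 36 h hypoxia with 0 h addressed the longest exposure. Secreted enzymes were among the highest named genes. An endoglucanase (AFUA_1G12560, sequence 95, 1072020 to 1073197) was at 15.4 RPKM at 0 h and 904 RPKM at 36 h, 58.8-fold (95% interval 51.1 to 68.1) higher, and the alkaline serine protease PR1, an allergen (AFUA_7G04930, sequence 99, 895626 to 897037), was at 2.45 and 199.5 RPKM, 81.5-fold (95% interval 59.1 to 116) higher. The RNA 3'-terminal phosphate cyclase (AFUA_5G07640) was 99.8-fold (95% interval 63.6 to 166) higher and a GNAT family acetyltransferase (AFUA_7G04960) 65.7-fold (95% interval 41.2 to 112) higher. Asp F2 was 69.03-fold (95% interval 52.6 to 92.5) higher and the copper ATPase 44.9-fold (95% interval 41.3 to 48.9) higher. At the other end, ribosomal protein S28e, of a span under 800 bp, was 429-fold (95% interval 119 to 3549) lower, a short-chain dehydrogenase/reductase (AFUA_1G14540, sequence 95, 1638350 to 1639362) 107-fold (95% interval 89.3 to 129) lower and the ribonuclease allergen Asp F1 (AFUA_5G02330) 15.9-fold (95% interval 12.2 to 21.1) lower. The S28e fold rests on few reads at 36 h, as its wide interval shows. Genes of spans under 800 bp were lower as a group at 36 h too.

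Secreted carbohydrate hydrolases had 37 of 73 members at least 2-fold higher at 36 h and 1 lower, with a median log2 difference of 1.11 and a percentile of 100. The pectate lyase plyE (AFUA_8G05910) was 108-fold (95% interval 41.6 to 399.6) higher. Conidia and melanin genes had a median of 1.49 (9 of 16 higher), among them the pigment genes pksP, at 41.3 RPKM, arp1 (AFUA_2G17580), 13.5-fold (95% interval 6.95 to 29.4) higher, and arp2 (AFUA_2G17560), 19.2-fold (95% interval 8.32 to 54.2) higher. Secondary metabolism backbones had a median of 1.25 (19 of 31 higher and 1 lower). Iron uptake and siderophores had a median of 1.09 (15 of 26 higher and 1 lower), with sidF (AFUA_3G03400) 112-fold (95% interval 30.4 to 936) higher. The ornithine oxygenase sidA lay -2.02 log2 units from the median of all genes at 36 h. Heat shock proteins and chaperones had a median of 0.64 with 15 of 30 higher and 7 lower, and stood at percentile 77.1 without spans under 800 bp and 84.1 with no filter on low values. Sugar transporters had a median of 0.63 and fermentation genes 0.55. A lactate dehydrogenase (AFUA_5G14800) was 8.52-fold (95% interval 7.13 to 10.2) higher. The fermentation list was at percentile 95.9 with a pseudocount of 0.1, 96.7 with a pseudocount of 10 and 94.9 without spans under 800 bp, and the sugar transporters at 92.6 for the list mean and 97.49 with no filter on low values.

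Among the gene lists at 36 h, the ribosomal and respiratory ones had the lowest medians. Of 96 cytosolic ribosomal protein genes, 88 were at least 2-fold lower, with a median of -1.98, for example the acidic protein P1 (AFUA_1G06830), 26.6-fold (95% interval 21.5 to 33.4) lower. Ribosome biogenesis genes had a median of -1.65 (55 of 66 lower) and mitochondrial ribosomal proteins -1.53 (15 of 21). On the deposited scale their medians at 12 h were -1.76 and -1.76, so neither list was lower at 36 h than at 12 h on that scale. Of the 59 nuclear respiratory chain and ATP synthase genes, 47 were at least 2-fold lower (median -1.66), while 6 of the 10 mitochondria-encoded ones were higher (median 1.72). A cytochrome c oxidase family gene (AFUA_3G14440) was 13.996-fold (95% interval 11.8 to 16.8) lower. Tricarboxylic acid cycle genes had a median of -0.97 (14 of 30 lower and 2 higher), proteasome genes -1.04 (20 of 39 lower), tRNA synthetases -0.93 (16 of 38) and DNA replication and histone genes -0.68 (11 of 35). The tricarboxylic acid cycle list, drawn up from product names, also held the leucine gene leu2A (AFUA_1G15780) and the lysine gene lysF (AFUA_5G08890), 3.64-fold (95% interval 3.16 to 4.1998) and 3.28-fold (95% interval 2.84 to 3.82) lower.

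In all, 1928 of 8829 measured genes were at least 2-fold higher at 36 h and 1597 at least 2-fold lower, or 744 and 306 at the 4-fold threshold and 948 and 961 with a pseudocount of 10.

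**Figure D4:**
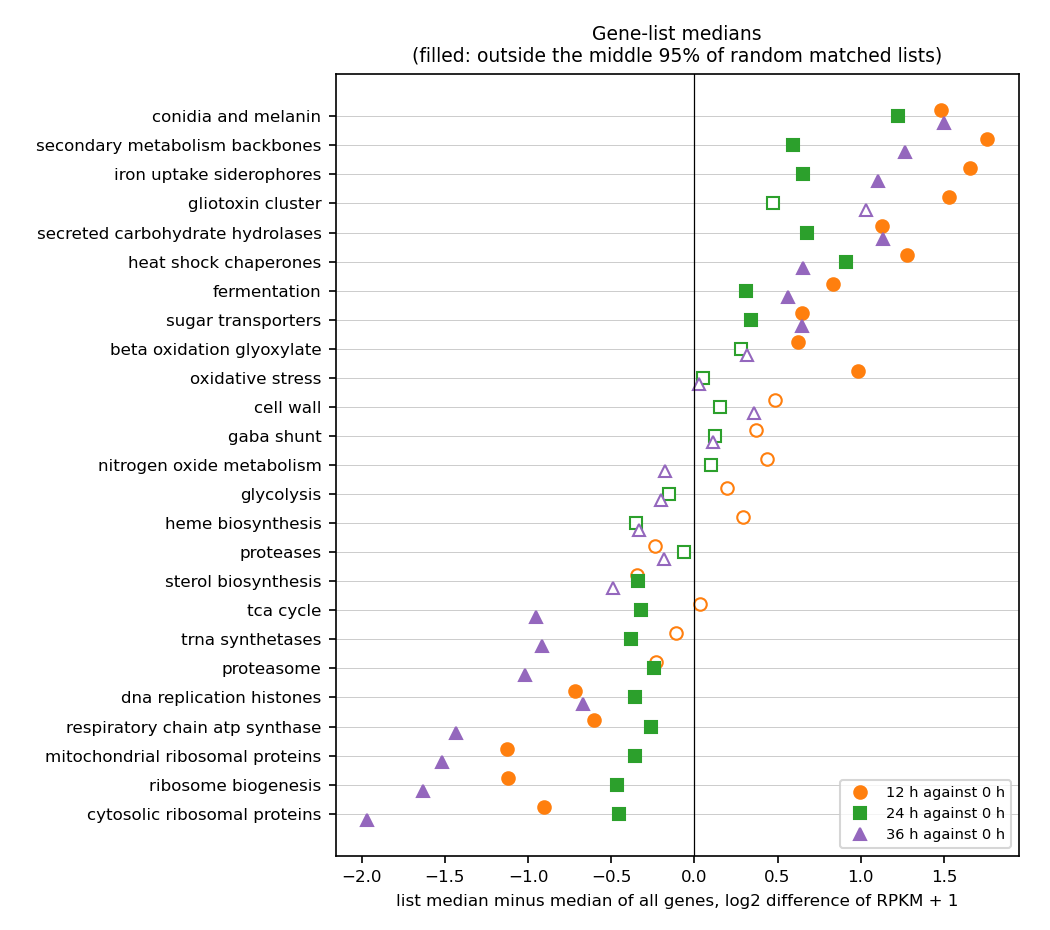
Median log2 difference of RPKM + 1 from 0 h of each gene list, minus the median of all genes (horizontal axis), for 12 h, 24 h and 36 h hypoxia. Filled symbols lie outside the middle 95% of 10000 random lists matched on expression. Conidia and melanin genes lie at 1.48, 1.22 and 1.503, and cytosolic ribosomal proteins at -0.91, -0.45 and -1.97. With median-of-ratios factors the conidia and melanin median at 12 h was 0.95.

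The medians of several lists depended on the filter and the pseudocount. Secondary metabolism backbones had medians of 0.20, 0.12 and 0.28 at 12, 24 and 36 h with a pseudocount of 10 and 0.31, 0.20 and 0.67 with no filter on low values, against 1.12, 0.50 and 1.25. Secreted carbohydrate hydrolases had 0.17, 0.18 and 0.34 with a pseudocount of 10 and 0.16, 0.30 and 0.70 with no filter, against 0.49, 0.58 and 1.11. With a pseudocount of 10 the medians were 0.13, 0.34 and 0.46 for conidia and melanin and 0.39, 0.34 and 0.57 for iron uptake, and with no filter conidia and melanin had 0.23 and the gliotoxin cluster 0.57 at 12 h.

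Several lists did not stand apart at any of the 3 times with the settings fixed for the comparisons. Medians at 12 h (relative to all genes), 24 h and 36 h were 0.20, -0.25 and -0.22 for glycolysis, where a hexokinase (AFUA_2G00450) was 16.1-fold (95% interval 11.7 to 22.8) higher at 24 h, and 0.29, -0.45 and -0.35 for heme biosynthesis. They were 0.43, 0.0076 and -0.19 for nitrogen oxide metabolism and 0.49, 0.061 and 0.34 for the cell wall, where a class V chitinase (AFUA_5G01400) was 29.2-fold (95% interval 23.3 to 37.1) higher at 36 h. They were 0.37, 0.033 and 0.10 for the GABA shunt, where 4-aminobutyrate transaminase gatA (AFUA_5G06680) was 12.4-fold (95% interval 10.7 to 14.5) lower at 36 h. For proteases they were -0.24, -0.15 and -0.20, but the list stood lower at 12 h with a pseudocount of 10, no filter on low values or no spans under 800 bp (percentiles 2.08, 1.26 and 2.42). At 24 h and 36 h the oxidative stress list (-0.043 and 0.0087), the beta-oxidation and glyoxylate list (0.19 and 0.30) and the gliotoxin cluster (0.38 and 1.013) did not stand apart, nor did sterol biosynthesis at 36 h (-0.51), the tricarboxylic acid cycle, tRNA synthetases and proteasome at 12 h (0.033, -0.11 and -0.23 relative to all genes). Of these, some stood apart for the list mean: oxidative stress at 24 h (percentile 98.8), sterol biosynthesis at 36 h (0.21) and tRNA synthetases and the proteasome at 12 h (1.5 and 0.23). With a pseudocount of 10 the proteasome at 12 h (2.06) and sterol biosynthesis at 36 h (2.12) stood lower.

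Across the course, 741 of 8900 genes measured in any of the 3 comparisons with 0 h were at least 2-fold higher at all 3 hypoxia times, and 44 were at least 2-fold lower. Independent lists of these sizes share 33.2 and 3.46 genes. Unchanged libraries simulated against the shared 0 h library gave means of 1.15 and 0.8 with counting error alone, 6.55 and 1.95 with an assumed coefficient of variation of 0.2 between cultures, and 183 and 98.4 with one of 0.4. The 44 lower genes thus did not exceed the simulated count at a coefficient of 0.4. Part of the 741 higher genes, and part or all of the 44 lower ones, may come from the shared 0 h library, which could not be split. Without the 24 h library, 1008 genes were higher and 1285 lower at both 12 h and 36 h, where independent lists share 264 and 549.8, so the 24 h library set the count of lower genes. Both of these comparisons use the shared 0 h library too, and no simulation was made for this pair. Part of their overlap beyond independent lists may therefore come from that library. Among the genes named above, the copper ATPase, Asp F2, the extracellular lipase, PR1 and the Hsp30/Hsp42 gene were higher at all 3 times.

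The comparison of 24 h with 12 h hypoxia followed the course of exposure. Ribosomal protein S28e was at 7.26 RPKM at 12 h and 402 RPKM at 24 h, 55.4-fold (95% interval 29.98 to 116) higher, and the short-chain dehydrogenase/reductase AFUA_1G14540 at 35.9 and 2021 RPKM, 56.3-fold (95% interval 48.98 to 64.96) higher. The indoleamine 2,3-dioxygenase family gene was 10.1-fold (95% interval 9.39 to 10.8) lower, and the mitochondria-encoded ATP synthase subunit 6 was 64.7-fold (95% interval 55.2 to 76.4) lower. Relative to the median of all genes, which lay 0.58 higher at 24 h, the lists that stood higher were cytosolic ribosomal proteins (0.38), mitochondrial ribosomal proteins (0.69), ribosome biogenesis (0.58) and the respiratory chain (0.20). In the respiratory chain list 11 members were at least 2-fold above the median of all genes and 12 below it: the median log2 difference on the deposited scale was 0.94 for the 59 nuclear genes and -2.51 for the 10 mitochondria-encoded ones, of which 8 were lower. Those that stood lower were gliotoxin (-1.29), iron uptake (-0.95), secondary metabolism backbones (-0.80), fermentation (-0.52), secreted carbohydrate hydrolases (-0.37) and sugar transporters (-0.19). The last 3 had positive medians on the deposited scale (0.059, 0.21 and 0.39), so their direction turned with the scaling. On the deposited scale 2577 of 8697 genes were at least 2-fold higher and 366 lower. The split was 1068 and 1133 with median-of-ratios factors, 1321 and 880 with TMM factors, and 1418 and 806 at the same upper quartile, and 930 and 180 with a pseudocount of 10. Sugar transporters were at percentile 4.76 for the list mean, 3.5 with no filter and 5.25 without spans under 800 bp. Cell wall genes stood lower with median-of-ratios factors and with no filter (percentiles 0.94 and 0.83), and sterol biosynthesis stood higher for the list mean and with a pseudocount of 10 (98.8 and 98.995).

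The comparison of 36 h with 24 h hypoxia followed the last step of exposure. A chitin binding protein gene (AFUA_1G14430) was 6.996-fold (95% interval 5.85 to 8.42) higher and a pectin lyase (AFUA_5G10380) 5.96-fold (95% interval 4.74 to 7.56) higher, while ATP synthase subunit 6 was 38.8-fold (95% interval 33.002 to 45.8) higher. S28e was 296-fold (95% interval 81.7 to 2447) lower, the protein translocation subunit Sss1 (AFUA_3G06901) 18.6-fold (95% interval 10.5 to 36.4) lower and the acidic ribosomal protein P1 16.8-fold (95% interval 13.5 to 21.1) lower. The S28e fold rests on the same few reads at 36 h. Of the lists, 75 of 96 cytosolic ribosomal proteins were at least 2-fold lower (median -1.49). Medians were -1.04 for ribosome biogenesis, -1.02 for the respiratory chain, -0.86 for mitochondrial ribosomal proteins, -0.69 for the proteasome, -0.62 for the tricarboxylic acid cycle and -0.43 for tRNA synthetases. Higher lists were secondary metabolism backbones (0.67), conidia and melanin (0.67), secreted carbohydrate hydrolases (0.57), iron uptake (0.49) and sugar transporters (0.30), and 3 lists stood higher without spans under 800 bp. Sugar transporters and conidia and melanin genes did not, at percentiles 96.9 and 88.8. Sugar transporters were also at percentile 94.6 with a pseudocount of 10, 70.8 for the list mean and 74.3 with no filter, and tRNA synthetases at 3.67 and DNA replication and histone genes at 0.41 for the list mean. The respiratory chain list again split, with medians of -1.10 for nuclear and 1.90 for mitochondria-encoded genes. In all, 590 of 8834 genes were at least 2-fold higher and 890 lower, or 190 and 431 with a pseudocount of 10.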

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

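The tests of depth, scaling, 0 h RNA, listed genes, library preparation and oxygen supply in this part were chosen only after the results were seen. The 3 rescalings themselves were among the alternatives fixed before, and only their use as a test here came after. Between time points, 40 genes with at least 10 RPKM in a library were at least 2-fold higher than 0 h at 1 hypoxia time and at least 2-fold lower at another. Of these, 32 were lower at 12 h and higher at 36 h, 13 were lower at 12 h and higher at 24 h, 4 were higher at 24 h and lower at 36 h, and 1 was higher at 12 h and lower later. These differences between times were not tested, since there was 1 library each. The count rests on the deposited scale, on which the median of all genes lay at -0.64 at 12 h. With each comparison set to its own median the count was 16, of which 13 were among the 40, and 7 were lower at 12 h and higher at 36 h. The conidiation factor flbC (AFUA_2G13770) had log2 differences from 0 h of -2.73, 1.12 and 0.19 at 12, 24 and 36 h. The spore catalase catA (AFUA_6G03890) had -1.005, -0.13 and 1.39, but lay -0.37 from the median of all genes at 12 h, which is under 2-fold. The mitochondria-encoded S5 ribosomal protein (AFUA_MITO001) had 3.03, -1.12 and 2.47.

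Few genes were lower at 24 h than at 0 h: 56, against 3064 at 12 h and 1597 at 36 h. Depth as the whole cause was argued against by thinning to the 12 h depth, which gave 81 genes. Under 3 rescalings the largest count was 47. They moved the 24 h library up by 0.018 to 0.086 log2 units against 0 h and so could not raise the count. The authors' scaling as a cause is therefore not decided by them. RNA of 0 h germlings in the 24 h library stays open: of 5337 well-covered genes, the 10th lowest ratio of 24 h to 0 h was 0.438, and 187 genes under 0.25 of their 0 h level at both 12 h and 36 h had a median ratio of 0.619 at 24 h. The prediction for this cause, a 10th lowest ratio at or above the lower quartile of the 187 genes (0.544), was not met. The ratio also stayed above the level set as speaking against this cause. Of the 5337 genes, 0 were under 0.25 at 24 h (lowest 0.343), against 741 at 12 h and 308 at 36 h. A true slower or partial response at 24 h would give such values too, and the design, with 1 library per time and the 24 h and 36 h cultures from 1 split starting culture, does not separate them. As a hypothesis only, the 24 h library may hold a share of 0 h RNA, and 69 genes over 1.5 times as high at 24 h as in every other library cannot come from 0 h RNA.

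Short genes were lower and genes of the mitochondrial genome higher at 12 h and 36 h than at 0 h and 24 h. The difference of short from long genes, matched on expression, was -0.60 (95% interval -0.69 to -0.49 over genes). Lower ribosomal, respiratory and other listed genes as the whole cause were argued against by -0.50 without the listed genes, and depth by -0.58 after thinning. Library preparation that differed between these pairs of libraries might give both parts, with 15 of 17 mitochondrial-genome genes higher at both 12 h and 36 h, but no batch is given in the labels. Poly(A) selection is a step of that preparation, and how it acted on mitochondrial transcripts was not tested. A response of the fungus that alternates between these times was not tested and cannot be told apart from a difference in library preparation. The medians of cytosolic ribosomal proteins (-1.54, -0.55 and -1.98 at 12, 24 and 36 h) and nuclear respiratory genes (-1.38, -0.38 and -1.66) followed the same pairs of libraries. The same limit therefore holds for these groups.

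Hypoxia-response genes were abundant at 0 h: of the 17 genes given by locus tag in 6 lists (sterol and heme synthesis, hypoxia regulators, fermentation, alternative oxidase and nitrogen oxide metabolism), 14 lay above the 95th percentile of all genes at 0 h, with a median percentile of 98.97. The lowest was the alcohol dehydrogenase alcA, at 7.48, and 13 of the 17 were at 0 h no lower than 0.5 of their highest hypoxia level, aoxA, alcC, pdcA and alcA being the others. In RPKM, cyp51A, cyp51B, erg25B, erg1, erg3B, hmg1, hem13 and niiA were higher at 0 h than in every hypoxia library. The rest of the 17 were highest in a hypoxia library. Oxygen could already have been limiting in the 0 h culture. No other gene list was set beside these genes at 0 h, so their abundance does not decide it. Handling before the harvest, or a high level that is usual for germlings, would give the same values, and no other normoxia library was there to separate these.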

How the results depend on the processing

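The alternatives of thinning, of leaving out the 24 h library and of leaving out spans under 800 bp were chosen after the data were seen, and the others before. No paired analysis was possible because each time point had 1 library. Where no reason is given, the cause was not tested. Of the 753 log2 differences of named genes that were at least 2-fold, 0 turned sign with other pseudocounts or median-of-ratios factors. This was fixed by construction and is no check. A pseudocount cannot change which of 2 values is larger, and median-of-ratios factors moved no comparison by over 0.664 log2 units. Of the 467 under 2-fold, 49 lay close enough to 0 to turn sign with the common shift of median-of-ratios factors, and none could turn with other pseudocounts. The values of at least 2-fold moved beyond their counting interval in 328 with median-of-ratios factors, 621 with a pseudocount of 10 and 0 with a pseudocount of 0.1. No list went from standing higher to standing lower or back, and 0 to 2 lists per comparison and setting no longer stood apart. Over the 750 placings of a list under an alternative, 28 lost their place apart and 16 gained one, with up to 3 gained per comparison and setting, both at 12 h (list mean and pseudocount of 10). Thinning to the 12 h depth moved 0 of the 10 counts of higher or lower genes by over 1.5 times.

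The 4-fold threshold is stricter by construction. It gave 523 higher and 755 lower at 12 h against 0 h, 392 and 0 at 24 h, 744 and 306 at 36 h, 416 and 65 for 24 h against 12 h, and 22 and 116 for 36 h against 24 h. A pseudocount of 10 shrinks low values by construction. It gave 712 and 1602, 510 and 10, 948 and 961, 930 and 180, and 190 and 431 in the same order, 346 higher and 9 lower at all 3 times, and 8 lists standing lower at 12 h, against 5. A pseudocount of 0.1 gave 89 lower genes at 24 h against 0 h. A larger value of at least 10 RPKM, which leaves fewer genes, gave 743 and 34 at 24 h against 0 h.

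Median-of-ratios factors gave 1998 and 1503 at 12 h against 0 h and 1068 and 1133 for 24 h against 12 h, as they lift the 12 h library. With them the list medians were 0.62 for beta-oxidation at 12 h, and -0.46 for fermentation, -0.32 for secreted carbohydrate hydrolases and -0.18 for sugar transporters in 24 h against 12 h, each of the opposite sign to the deposited scale. TMM factors gave 1883 and 1627 at 12 h against 0 h, 1321 and 880 for 24 h against 12 h, and 31 lower at 24 h against 0 h. The same upper quartile gave 1855 lower at 12 h against 0 h, and 1418 and 806 for 24 h against 12 h.

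List means at 12 h against 0 h were 0.070 for beta-oxidation and -0.0082 for sugar transporters, with 8 lists standing lower. With no filter on low values the sugar transporter median at 12 h was -0.019. Without spans under 800 bp the medians at 12 h were -0.45 for conidia and melanin and -0.17 for oxidative stress, and 3 lists stood higher in 36 h against 24 h. Without the 24 h library 1285 genes were lower at both remaining times. Depth limits low genes most: a gene of 1 kb with 3 reads at 12 h stands at 0.5403 RPKM.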

Other observations

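The test of neighbouring genes in this part was chosen after the genes higher at all 3 times had been counted, and the genes and regions named here were chosen after their values were seen. Some of the genes at least 2-fold higher than 0 h at all 3 hypoxia times lay next to each other. There were 11 runs of at least 5 neighbours, with 60 of the 741 genes and a longest run of 7. In 1000 shuffles of gene order the mean was 0.011 runs and the highest was 1. Shared regulation of neighbouring genes is thus a hypothesis that these 11 runs allow but that rests on the same data it was found in.

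The longest run lay on sequence 93, from 463452 to 478176, with 7 genes (AFUA_3G13640 to AFUA_3G13700) and median log2 differences of 4.18, 1.86 and 3.27 at 12, 24 and 36 h. It held crmD, crmC, annotated as a siderochrome-iron transporter, and a pyoverdine/dityrosine biosynthesis family gene, and its other 4 genes were a transferase family gene, a conserved hypothetical gene, an integral membrane protein gene and an extracellular serine-rich protein gene. A run on sequence 57, from 1160599 to 1174172, held genes of tyrosine degradation, with medians of 3.20, 3.83 and 3.54. The 4-hydroxyphenylpyruvate dioxygenase hppD (AFUA_2G04200) stood at 2.25, 88.7, 73.9 and 81.4 RPKM at 0, 12, 24 and 36 h, and homogentisate 1,2-dioxygenase hmgA (AFUA_2G04220) at 5.82, 23.9, 18.95 and 17.6 RPKM. A run on sequence 100, from 144990 to 153549, held the peptidase lap2 (AFUA_3G00650) and a copper amine oxidase (AFUA_3G00680), with medians of 4.36, 4.06 and 4.04. Other runs ended at the pigment gene abr2, at the pyruvate decarboxylase pdcC (AFUA_5G14810, 52.98, 207, 117 and 342 RPKM) and next to Lot6.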
